A study of Mus musculus with 15 samples.

How the data were processed

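The data are bulk RNA-seq profiles of 15 mouse kidney samples, 5 each from microdissected cortex, outer medulla and inner medulla, sequenced as paired-end Illumina libraries from total RNA, per the labels' protocols. The authors deposited 1 table with a TPM value for each of 25030 gene symbols in each library. STAR and the mouse build mm9 are named, per the submitters' processing notes, without a version for the aligner. The counting tool, the annotation and the library's strand setting are not given in the sources used here. Reads of genes that overlap, lie antisense or have near-identical copies can therefore not be told apart, and no coordinates are printed. The table has 92 rows of ERCC spike-in names, all at 0, so it carries no absolute scale. Rows named as microRNA or small nucleolar RNA genes (1279 rows) held 2.91% to 4.87% of the TPM. By zone the mean share was 2.95% in cortex (SD 0.044), 3.04% in OM (SD 0.047) and 4.34% in IM (SD 0.307). Such short rows can collect reads of their host genes.

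TPM divides reads by gene length and by a total, so it does not state depth. Every library's column summed to 1000000. Between libraries, however, genes with few reads shared the same ratio, which is what whole reads give after division by a fixed gene length and a library total. From these ratios, whole reads were recovered for all 19997 genes above 0 in at least 2 libraries (100%, within 0.001 of a whole number in every library), leaving out 762 genes above 0 in a single library. The recovered totals of 16264486 to 25195553 are reads assigned to genes. The recovery returned 100% of 3995 simulated genes exactly.

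The design had been laid out for a table of counts or of normalized values before the data were examined, and the branch for normalized values was used because the table holds TPM. Genes at 1 TPM or more in at least 5 libraries were kept (15052 genes), log2(TPM + 1) was taken, and limma 3.58.1 in R 4.3.3 fitted all 15 libraries together, with zone as the only factor and empirical Bayes moderation with trend and robust settings (statmod 1.5.0). The contrasts were OM minus cortex, IM minus OM and IM minus cortex, with Benjamini-Hochberg adjustment over the genes tested and calls at an adjusted p under 0.05. All tests were two-sided. A gene counted as enriched in a zone when it was called with a log2 difference of at least 1 over each of the other zones, and gradient classes were read from the signs of the called OM minus cortex and IM minus OM differences.

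Gene lists were fixed before the data were examined, 16 of cell types and 9 of pathways. The cell type lists were podocyte, convoluted proximal tubule, straight proximal tubule, thin limb, thick ascending limb, distal convoluted and connecting tubule, principal cell, intercalated cell, urothelium, endothelium, interstitial fibroblast and matrix, smooth muscle and renin, leukocyte, adipocyte, adrenal cortex and erythroid. The pathway lists were osmoadaptive genes, water and urea transport, glycolysis, gluconeogenesis and fructose use, fatty acid oxidation, oxidative phosphorylation, hypoxia response, prostaglandin synthesis and receptors, and immediate early genes. Some genes stand in more than 1 list (Aqp2, Aqp3, Aqp4, Aqp6, Avpr2, Slc14a1 and Ptger3). Lists with at least 3 tested members were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the 24 lists tested, and again with an estimated correlation and with fry. The rise and fall of members were counted from limma over all genes and adjusted over the list alone. The genes named were set by a rule. It takes the 6 largest rises and falls per comparison among called genes at a mean of at least 20 TPM in the higher zone, with no overlap between libraries, leaving out predicted genes. It adds 16 landmark genes, the up to 3 most abundant members of each list and members that moved against the majority of their list. Outside this rule the report names Kap, Napsa, Crot, Klhl3, Hspa1a and Gm6644, picked after their values were seen. The closing section adds Adipoq, a member of the adipocyte list, and the Wnt, Hox, claudin and keratin genes named under its other observations, apart from Cldn4, and these were also picked after their values were seen. A landmark gene and some list members are not reported here.

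The tests were tried on simulated reads drawn from the means and spreads of the recovered reads in the second zone of each comparison, with known changes put into genes of at least 20 reads on average. In the OM and cortex simulation (13967 genes), 96% of genes changed 2-fold and 98% of those changed 4-fold were called, and 5.4% of calls were false. In the IM and OM simulation (14477 genes) these were 94%, 99% and 5.4%, and in the IM and cortex simulation (13981 genes) 96.8%, 100% and 3.1%. A raised list was called in each simulation and 0 of 25 unchanged lists were. The simulated genes were drawn independently, few were changed, and equal numbers rose and fell. In the real data the estimated correlation within a list reached 0.907 (erythroid), and most genes changed between IM and the other zones. These rates may therefore not carry over to the real lists and counts.

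Alternatives set in advance were the replicate number as a block, each library left out in turn, pairwise fits, a pseudocount of 0.1, no filter, quantile normalization, and the list tests above. Chosen after seeing the data were median-ratio scaling, limma voom on the recovered reads and a fit without the 3 libraries that stood apart in marker levels (cortex 1, OM 1 and IM 4). No pair of libraries agreed within sampling noise, since the lowest mean chi-square per gene within a zone was 4.16, so all 15 were used. Calculations outside R and the figures used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.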

Results

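Gene expression was measured by bulk RNA sequencing in 3 microdissected zones of the mouse kidney: the cortex, the outer medulla (OM) and the inner medulla (IM). Total RNA came from wild-type male mice, with the strain labelled C56BL/6N. Each zone has 5 libraries, 15 in all. The table held 25030 genes in TPM (transcripts per 1000000), a unit in which every library has the same total of 1000000. Whole reads could be recovered from the steps between low TPM values. They gave 16264486 to 25195553 reads assigned to genes per library. A gene at 1 TPM rested on a median of 20.9 to 33 reads, depending on the library. Levels are mean TPM over the 5 libraries of a zone, with ± for the SD. Changes are differences of log2(TPM + 1) with their standard error, which understate the change of genes with few transcripts. The labels do not say that the 5 libraries of a zone came from separate animals. The adjusted p-values of limma therefore measure the spread between these libraries, which may be technical. The study's title points to its question, how expression is ordered along the axis from cortex to papilla and along the osmolality gradient.

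IM stood far from the other zones, and cortex and OM lay closer together. The first principal component held 82.8% of the variance of log2(TPM + 1) and the second 6.4%. Libraries of the same zone correlated across all 25030 genes at 0.990 to 0.996, and pairs from different zones at 0.9144 to 0.9904, so these ranges overlap: cortex library 1 and OM library 2 correlated at 0.9904, and IM library 4 with IM libraries 1 and 5 at 0.99. Genes are not independent replicates. Kap, an androgen-regulated transcript of the proximal tubule, was the most abundant gene in 14 of the 15 libraries and took 7.35 ± 0.658% of all TPM in cortex, 8.73 ± 0.338% in OM and 2.67 ± 1.01% in IM. The 100 most abundant genes took 32.7 ± 0.148%, 30.4 ± 0.259% and 21.4 ± 0.809%. On the TPM scale the typical gene stood higher in IM. The median of all 15052 tested genes lay 0.114 above 0 (log2) between OM and cortex, 0.514 between IM and OM and 0.652 between IM and cortex. Median-ratio scaling, in which each library is divided by the median ratio of its genes to their geometric mean over libraries, brought these medians to -0.02, 0.02 and 0.03. Counts and values are therefore given on the TPM scale and again after this scaling, which states them relative to the typical gene.

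**Figure D1:**
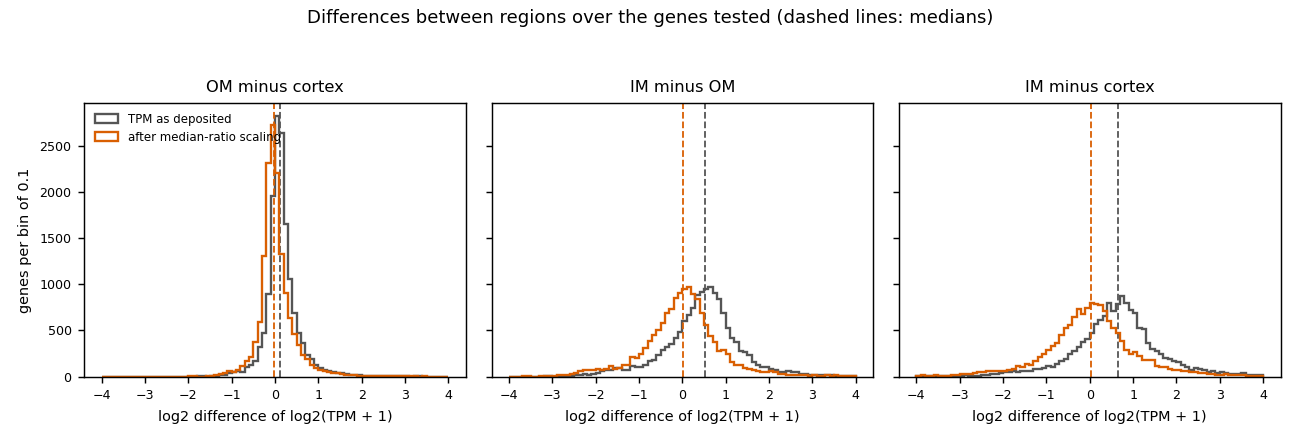
Histograms of the difference in log2(TPM + 1) over the 15052 tested genes for each pair of zones, on the TPM scale (grey) and after median-ratio scaling (orange), with the x axis in log2 units limited to 4 on either side and the y axis in genes per bin of 0.1. Dashed lines mark the medians, which on the TPM scale were 0.114, 0.514 and 0.652.

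The first comparison asked which transcripts distinguish the outer medulla from the cortex. OM held more transcripts of the thin limb and of water and urea transport, and fewer of the convoluted proximal tubule and of the distal convoluted and connecting tubule. These 4 lists were the ones still called with an estimated correlation, each at adjusted p = 0.0492. Slc14a2, which encodes the urea transporters of the collecting duct and thin limb, was 0.133 ± 0.165 TPM in cortex and 39.8 ± 8.05 TPM in OM (log2 5.16, SE 0.13, adjusted p = 6.3e-13, n = 5 per zone). Slc12a1, the sodium-potassium-chloride cotransporter of the thick ascending limb, was 5.77-fold higher in OM, at 157 ± 23.9 against 906 ± 176 TPM (log2 2.51, SE 0.23, adjusted p = 2.03e-06). Slc5a2, the glucose cotransporter of the early proximal tubule, was 2.21-fold lower, at 689 ± 60.5 against 312 ± 38.7 TPM (log2 -1.15, SE 0.12, adjusted p = 3.47e-06).

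The largest rises in OM were those of Slc14a2, Nccrp1 (5.84 to 155 TPM), Lypd2 (0.493 to 25.9 TPM), Cck, the gene of the peptide cholecystokinin (0.464 to 22.5 TPM), Bcat1, a branched-chain amino acid aminotransferase (3.64 to 46.2 TPM), and Akr1c18, an aldo-keto reductase that acts on steroids (5.25 to 61.3 TPM). The largest falls were smaller. They were those of Ces1g, a carboxylesterase (36.1 to 9.55 TPM), Pvalb, the calcium-binding protein parvalbumin (90.5 to 27.5 TPM), S100g, a calbindin (2644 to 995 TPM), Clec2h (94.5 to 35.5 TPM), the kallikrein gene Klk1b5 (33.7 to 12.7 TPM) and Slc5a12, a lactate cotransporter of the proximal tubule (156 to 60.3 TPM). All 12 kept their direction after scaling. Klk1b5 belongs to a family of similar kallikrein genes, so its reads are less certain.

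All 12 tested genes of the convoluted proximal tubule list fell in OM, also after scaling and adjusted over the list alone, with Slc34a1, the main phosphate cotransporter, at 5175 ± 427 against 2826 ± 424 TPM and Cyp2e1 at 2840 ± 204 against 1339 ± 197 TPM (camera, adjusted p = 2.49e-17, and adjusted p = 0.0492 with an estimated correlation). Of the 12 genes of the distal convoluted and connecting tubule, 11 fell and Klhl3 did not pass (log2 -0.68, adjusted p = 0.0718 in limma), while 12 fell after scaling and adjusted over the list alone. Camera gave adjusted p = 8.42e-15, and 0.0492 with an estimated correlation. Among them Slc12a3, the thiazide-sensitive sodium chloride cotransporter, went from 583 ± 109 to 287 ± 86.2 TPM and Klk1, tissue kallikrein, from 4846 ± 484 to 2077 ± 456 TPM.

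Of 8 thin limb genes 6 rose, on both scales and over the list alone, led by Cryab, a small heat shock protein (49.8 ± 26.6 to 313 ± 105 TPM). OM library 1 stood apart with a list level of 4.69 against 4.09 to 4.20, while cortex lay at 2.06 to 2.43. Cldn4 was 23.5 against 20.9 TPM without passing. The list gave adjusted p = 2.89e-05, and 0.0492 with an estimated correlation. Of 10 water and urea transport genes 8 rose on both scales and over the list alone, among them Aqp2, the vasopressin-regulated water channel (233 ± 38.2 to 465 ± 66.8 TPM), and Aqp1, the water channel of proximal tubule and descending limb (509 ± 55.2 to 875 ± 63.0 TPM). The list gave adjusted p = 2.89e-05, and 0.0492 with an estimated correlation. The other 9 lists called by camera lost the call with an estimated correlation. Of 10 thick ascending limb genes 8 rose (7 after scaling, 9 adjusted over the list alone), including Umod, uromodulin, at 942 ± 109 against 3285 ± 901 TPM, and 1 fell (adjusted p = 0.000187, and 0.25 with an estimated correlation).

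Of 8 straight proximal tubule genes 6 rose (5 after scaling, 7 adjusted over the list alone), such as Acsm3 (507 ± 152 to 1051 ± 152 TPM), while the amino acid transporter Slc7a13 stood at 841 ± 163 and 1324 ± 135 TPM without passing (adjusted p = 0.0624 in limma). This list was called at adjusted p = 0.034, with 0.596 under an estimated correlation, and the call was lost without cortex library 2 (0.0515) or OM library 1 (0.059). Its mean level ranged from 6.36 to 8.16 (log2) over the cortex libraries, with cortex library 1 the highest, and from 8.67 to 8.99 over OM. All 8 tested urothelial genes rose on both scales and over the list alone, from low levels such as 0.471 to 3.78 TPM for Upk3b (adjusted p = 0.00284, and 0.344 with an estimated correlation). OM library 1 stood above the others with a list level of 3.11 against 1.32 to 1.87.

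Among cells outside the tubule, 9 of 10 endothelial genes rose (8 after scaling, 10 adjusted over the list alone), including the fenestral diaphragm gene Plvap at 81.4 ± 4.45 against 169 ± 15.5 TPM (adjusted p = 1.71e-05, and 0.165 with an estimated correlation). Of 10 interstitial fibroblast and matrix genes 9 rose on both scales and over the list alone, such as Col1a2 (12.3 to 28.4 TPM) and the decorin gene Dcn (12.1 to 37.2 TPM). The list gave adjusted p = 2.89e-05, and 0.133 with an estimated correlation. Osmoadaptive genes, which help cells withstand high tonicity, rose in 8 of 11 cases (4 after scaling, 8 over the list alone; adjusted p = 0.00327, and 0.103 with an estimated correlation). Slc5a3, the inositol transporter, went from 12.4 ± 0.825 to 52.0 ± 6.64 TPM and Slc6a12, the betaine transporter, from 0.0849 ± 0.0762 to 3.92 ± 0.999 TPM. Aldose reductase, Akr1b3, was 67.0 ± 9.91 and 91.1 ± 33.2 TPM (adjusted p = 0.189 in limma), with OM library 1 at 148 against 67.7 to 87.4 TPM in the others.

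Intercalated cell genes went both ways: 3 of 11 rose (4 adjusted over the list alone) and 7 fell, with 3 and 7 after scaling (camera, down, adjusted p = 0.000561, and 0.25 with an estimated correlation). Those that rose were the anion exchanger Slc4a1 (15.8 to 27.6 TPM) and Aqp6 (29.3 to 72.7 TPM), both known from acid-secreting type A cells, and the transcription factor Dmrt2 (2.56 to 4.57 TPM). Of 9 genes of gluconeogenesis and fructose use 3 fell and 6 did not pass, on both scales and over the list alone, with Pck1 at 1223 ± 244 and 1019 ± 157 TPM. Camera gave adjusted p = 0.00207, and 0.25 with an estimated correlation. The call was lost at 0.161 under quantile normalization. None of 7 adipocyte genes passed by limma, over all genes or adjusted over the list alone. Camera called the list lower at adjusted p = 0.00354, with 0.39 under an estimated correlation, 0.0923 after scaling, where 2 fell, and 0.088 under quantile normalization. Cortex library 2 held the highest adipocyte level of its zone, 4.90 against 2.05 to 3.79.

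In the main test camera did not call the remaining lists. Of 10 principal cell genes 5 rose and 2 fell, on the TPM scale and over the list alone, with 5 and 4 after scaling. The falls were those of the sodium channel subunits Scnn1b (50.1 to 31.5 TPM) and Scnn1g (36.6 to 23.8 TPM). The podocyte list averaged 3.4 in cortex and 3.36 in OM, as mean log2(TPM + 1). Cortex tissue in the OM pieces would give such similar levels, but it was not tested. Counts of rises and falls were 0 and 1 of 10 for podocytes, and 2 and 0 of 7 for smooth muscle and renin (1 and 0 after scaling). They were 4 and 0 of 10 for leukocytes (7 and 0 adjusted over the list alone, 2 and 0 after scaling), 2 and 0 of 7 for erythroid genes (0 over the list alone and after scaling) and 1 and 0 of the 2 tested adrenal cortex genes, too few for camera. For the pathway lists they were 7 and 1 of 16 for glycolysis (6 and 3 after scaling), 3 and 2 of 14 for fatty acid oxidation (2 and 4 after scaling), 0 and 1 of 15 for oxidative phosphorylation (0 and 2 after scaling), 4 and 2 of 10 for hypoxia (2 and 3 after scaling), 5 and 1 of 8 for prostaglandins (4 and 1 after scaling) and 1 and 0 of 9 for immediate early genes (0 over the list alone and after scaling). After scaling camera also called leukocytes (up, adjusted p = 0.0378), prostaglandins (up, 0.014) and oxidative phosphorylation (down, 0.0426). Quantile normalization called glycolysis (up, 0.00153, against 0.303 in the main test), leukocytes (up, 0.0369) and prostaglandins (up, 0.0254), and the fit with no filter leukocytes (0.0349) and prostaglandins (0.0155). The podocyte list was called lower without cortex library 1 (0.0448), without OM library 4 (0.0434) or without cortex 1, OM 1 and IM 4 together (0.0287), against 0.0809 with all. Prostaglandins were called without OM library 4 (0.0433), IM library 2 (0.0445) or IM library 5 (0.0469), against 0.0722. With the replicate number as a block, camera called the erythroid list higher (0.00497, against 0.406). Camera pointed down while median and mean lay above 0 in the fatty acid oxidation, oxidative phosphorylation, hypoxia and immediate early lists.

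In limma 5216 of 15052 genes changed between OM and cortex, 4267 higher and 949 lower in OM, and after scaling 5040 changed, 2481 higher and 2559 lower. At least a 2-fold change was met by 495 genes higher and 72 lower, or 416 and 145 after scaling, 331 and 124 under quantile normalization, 940 and 123 with the pseudocount 0.1 and 935 and 137 in voom. On the TPM scale the libraries of the zones did not overlap for 4317 genes (28.7%, where chance gives 0.79%). Overlap was not counted after scaling. As many lists as the 13 called here were called in 14 of 100 drawn splits of the 10 libraries, the real split included.

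**Figure D2:**
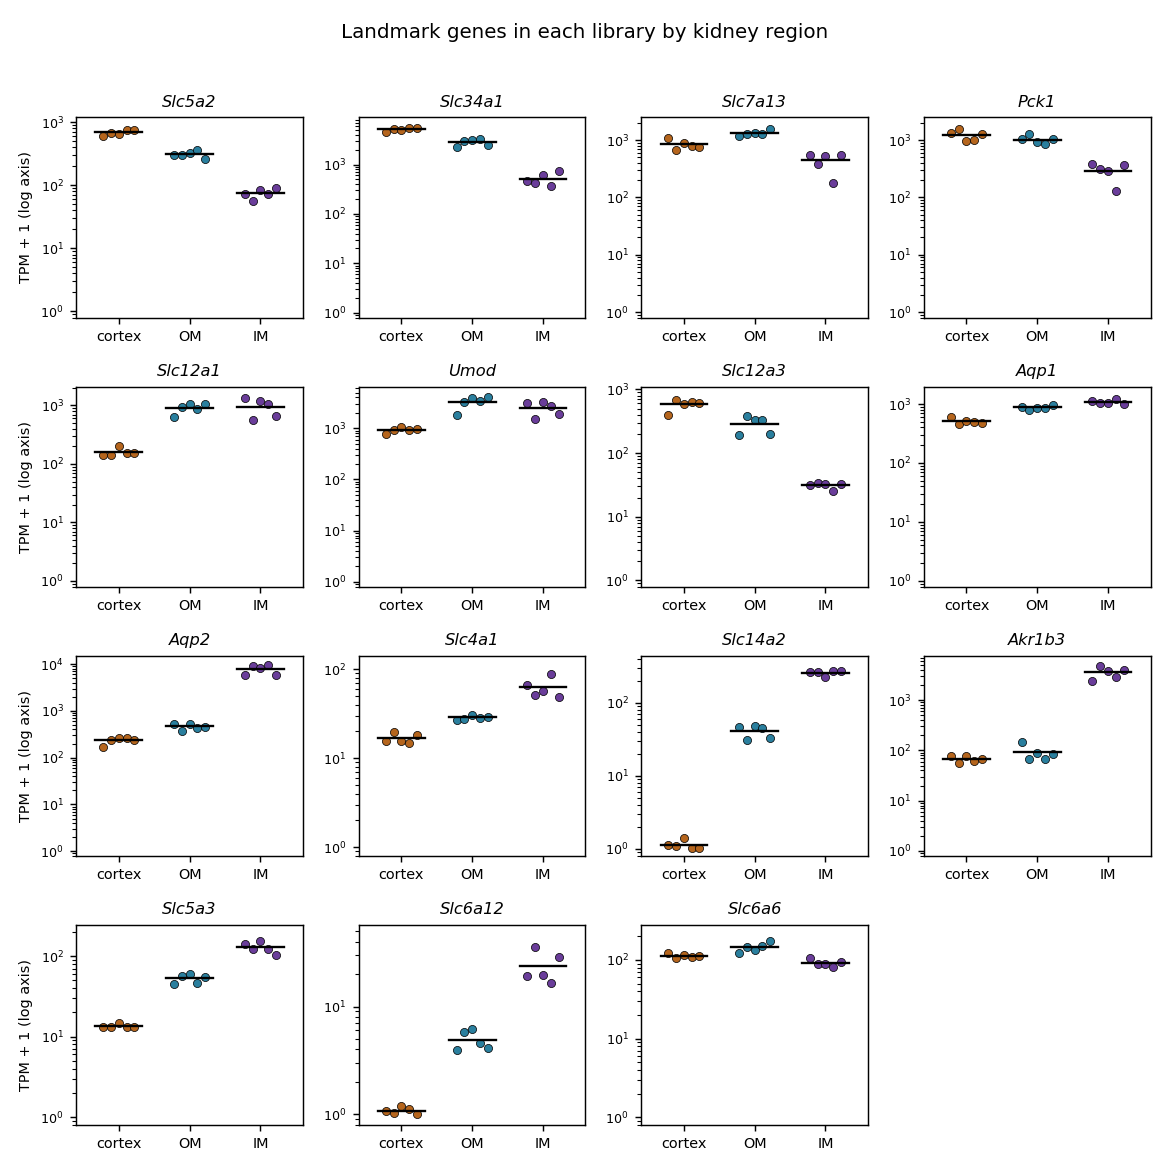
TPM + 1 on a log axis for 15 landmark genes fixed in advance in each library of cortex, OM and IM, with 1 point per library and the mean as a bar (n = 5 per zone). Aqp2 averaged 233, 465 and 7744 TPM in cortex, OM and IM, while Slc34a1 averaged 5175, 2826 and 516 TPM; all are on the TPM scale.

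The second comparison asked how the inner medulla differs from the outer. The water channel gene Aqp2 and the aldose reductase gene Akr1b3 were far higher in IM, and the phosphate cotransporter gene Slc34a1 was far lower. Of the gene lists, 0 stayed called with an estimated correlation. Aqp2 was 16.6-fold higher in IM, at 7744 ± 1685 against 465 ± 66.8 TPM (log2 4.04, SE 0.16, adjusted p = 7.38e-12; 3.49 after scaling). Akr1b3, which makes the osmolyte sorbitol, was 39.5-fold higher, at 3600 ± 944 against 91.1 ± 33.2 TPM (log2 5.31, SE 0.22, adjusted p = 2.8e-11; 4.77 after scaling). The predicted gene Gm6644 had similar values (3733 TPM in IM), and the reads of the pair are uncertain. Slc34a1 was 5.47-fold lower, at 516 ± 147 TPM (log2 -2.48, SE 0.16, adjusted p = 1.04e-09; -3.02 after scaling).

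The largest rises in IM over OM were those of Aldh1a3, a retinaldehyde dehydrogenase (2.24 to 317 TPM), Psca, a surface antigen (10.2 to 778 TPM), the claudin gene Cldn11 (0.504 to 108 TPM), Sptssb, a subunit of serine palmitoyltransferase (1.93 to 133 TPM), the adhesion receptor Adgrf1 (0.298 to 77.3 TPM) and Fcgbp (1.22 to 121 TPM). In OM library 1, Psca stood at 37.0 TPM against 1.66 to 5.00 in the other OM libraries, and Aldh1a3 and Sptssb were also highest there. The largest falls were those of S100g (995 to 96.1 TPM), Slc26a4, the anion exchanger pendrin of type B intercalated cells (35.5 to 3.01 TPM), Slc12a3 (287 to 30.2 TPM), Calb1, calbindin (159 to 17.1 TPM), Pvalb (27.5 to 2.13 TPM) and Tmem52b (84.8 to 9.37 TPM). All 12 kept their direction after scaling.

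Osmoadaptive genes rose in 10 of 11 cases on both scales and over the list alone. Besides Akr1b3, Hspa1b, an inducible heat shock protein, went from 17.4 ± 2.25 to 517 ± 185 TPM, Sgk1, a salt-regulated kinase, from 19.3 ± 3.94 to 344 ± 82.3 TPM and Slc5a3 from 52.0 ± 6.64 to 128 ± 19.3 TPM. The exception was the taurine transporter Slc6a6, which fell from 144 ± 20.2 to 90.7 ± 8.79 TPM. The list was called at adjusted p = 0.032, with 0.223 under an estimated correlation. Hspa1b has a near-identical copy, Hspa1a, and the reads of the pair are uncertain. Endothelial genes rose in 9 of 10 cases on both scales and over the list alone, with 1 falling after scaling. Examples were Emcn, endomucin (76.9 ± 14.0 to 587 ± 62.3 TPM), and Plvap (169 ± 15.5 to 676 ± 117 TPM). The list was called at adjusted p = 0.027, with adjusted p = 0.491 under an estimated correlation.

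No other list was called upward on the TPM scale. Even so, 8 of 10 principal cell genes rose (7 after scaling, 8 over the list alone), with Fxyd4 at 219 ± 79.2 against 1798 ± 374 TPM (adjusted p = 0.091). Of the thin limb list, 6 of 8 genes rose on both scales, with 1 falling after scaling and Cryab at 313 ± 105 against 5532 ± 1261 TPM (adjusted p = 0.152). All 8 urothelial genes rose on both scales, with Upk3b at 3.78 against 124 TPM (adjusted p = 0.0579). OM library 1 was the highest of OM for all 8, and the list was called without it (0.0182) or without cortex 1, OM 1 and IM 4 together (0.0242). With all libraries it was called in voom (0.0373), with no filter (0.0184) and with the replicate block (0.0383). Likewise 8 of 10 water and urea transport genes rose, or 7 with 3 falling after scaling, while Aqp7 and Aqp11 fell (adjusted p = 0.316). Scaling brought the first 3 of these 4 lists past the threshold, at adjusted p = 0.0152, 0.0173 and 0.00264, and left water and urea transport at 0.0573. Quantile normalization called all 4, at 0.0049, 0.0191, 0.00329 and 0.0149, and the fit with no filter called the principal cell list at 0.0311.

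All 12 convoluted proximal tubule genes fell in IM on both scales and over the list alone, with Cyp2e1 at 1339 against 206 TPM (adjusted p = 8.42e-13, and 0.157 with an estimated correlation). Of 8 straight proximal tubule genes 6 fell (8 after scaling and adjusted over the list alone), with Slc7a13 at 1324 ± 135 against 442 ± 165 TPM (adjusted p = 3.76e-05, and 0.322 with an estimated correlation). In IM library 4 the level of this list was 6.04, against 7.35 to 7.82 in the other IM libraries. Of 12 distal convoluted and connecting tubule genes 11 fell (12 after scaling, 11 over the list alone), with Klk1 at 2077 against 264 TPM (adjusted p = 2.73e-11, and 0.157 with an estimated correlation). Of 10 podocyte genes 5 fell and 2 rose, Cdkn1c and Podxl, of which Podxl fell after scaling (log2 0.22 against -0.31). After scaling 9 fell and 1 rose (adjusted p = 0.00272, and 0.198 with an estimated correlation).

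All 15 oxidative phosphorylation genes fell on both scales and over the list alone, 13 under quantile normalization, with the ATP synthase subunit Atp5b at 3562 ± 186 against 2452 ± 234 TPM (adjusted p = 3.84e-11, and 0.157 with an estimated correlation). Of 14 fatty acid oxidation genes 11 fell (14 after scaling), with Acadm, medium-chain acyl-CoA dehydrogenase, at 1436 ± 124 against 689 ± 208 TPM (adjusted p = 2.32e-08, and 0.157 with an estimated correlation). Of 9 genes of gluconeogenesis and fructose use 7 fell (8 after scaling), with Fbp1, fructose bisphosphatase, at 1320 ± 70.7 against 385 ± 138 TPM. IM library 4 stood apart with a list level of 6.43 against 7.18 to 7.48, while OM lay at 8.38 to 8.55. The mitochondrial Pck2 rose from 10.7 to 22.6 TPM (adjusted p = 1.97e-05, and 0.157 with an estimated correlation). Intercalated cell genes split again, 5 of 11 rising, Slc4a1 and Aqp6 (72.7 to 190 TPM) among them, and 4 falling, Slc26a4, Hmx2, Insrr and Slc4a9, with 3 and 6 after scaling. Their call was lost with an estimated correlation, after scaling, under quantile normalization, in voom on the recovered reads and without IM library 5 (adjusted p = 0.0297, against 0.491, 0.184, 0.114, 0.0706 and 0.0523). Of 10 leukocyte genes 4 fell and 2 rose, Cd68 and Lyz2, with 7 and 0 after scaling, where Lyz2 stood at log2 -0.01 (adjusted p = 0.0143, 0.491 with an estimated correlation, 0.0693 after scaling and 0.0704 under quantile normalization).

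Of the remaining lists, none called in the main test, thick ascending limb genes stayed near their OM level on the TPM scale. Of 10, 3 rose and 2 fell, with 2 and 6 after scaling, and Slc12a1 was 906 ± 176 and 958 ± 336 TPM in OM and IM (log2 0.02, SE 0.23, and -0.52 with adjusted p = 0.0476 after scaling). All 9 tested immediate early genes rose (6 after scaling), with Btg2 at 11.5 against 71.4 TPM (camera, adjusted p = 0.195). Of 8 prostaglandin genes 5 rose and 0 fell (4 and 2 after scaling), such as the receptor Ptger1 (48.5 to 338 TPM) and the synthase Ptges (11.7 to 117 TPM). Counts of rises and falls were 10 and 3 of 16 for glycolysis (6 and 8 after scaling, when Aldoa lay at log2 -0.01), 6 and 4 of 10 for hypoxia (4 and 4), and 4 and 3 of 10 for fibroblast and matrix genes (3 and 5). They were 1 and 1 of 7 for smooth muscle and renin (1 and 4; called lower at 0.0377 without IM library 1, against 0.0813), 3 and 0 of 7 for adipocyte genes (1 and 0), 0 and 0 of 7 for erythroid genes (0 and 5), and 1 and 1 of 2 for adrenal cortex genes (0 and 1). In IM library 4 the adipocyte level was 5.59, against 2.70 to 3.85 in the other IM libraries. With the replicate block, camera called the smooth muscle and renin list lower (0.0421). Adjusted over the list alone, every count of this comparison was as over all genes except that of the straight proximal tubule. Camera pointed down while median and mean lay above 0 for the thick ascending limb, fibroblast, adipocyte, glycolysis and hypoxia lists.

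In limma 12591 of 15052 genes changed between IM and OM, 9999 higher and 2592 lower in IM, and after scaling 11204 changed, 5706 higher and 5498 lower. At least a 2-fold change was met by 3256 genes higher and 909 lower, or 1445 and 1632 after scaling and 1391 and 1628 under quantile normalization. On the TPM scale, which holds the shift of the typical gene, the zones did not overlap for 10752 genes (71.4%, where chance gives 0.79%). Of the 11 lists called, 0 held with an estimated correlation, and 43 of 100 drawn splits of the 10 libraries called as many.

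The third comparison set the ends of the axis against each other, IM against cortex. Aqp2 was 33.2-fold higher in IM (log2 5.03, SE 0.16, adjusted p = 2.42e-13; 4.33 after scaling). Cryab was 111-fold higher (49.8 ± 26.6 to 5532 ± 1261 TPM; log2 6.86, SE 0.29, adjusted p = 1.34e-11; 6.17 after scaling) and Slc5a3 10.3-fold (log2 3.25, SE 0.10, adjusted p = 1.73e-13; 2.58 after scaling). Slc34a1 fell from 5175 ± 427 to 516 ± 147 TPM (log2 -3.36, SE 0.16, adjusted p = 1.74e-11; -4.06 after scaling) and Slc12a3 was 19.3-fold lower (log2 -4.21, SE 0.19, adjusted p = 3.13e-11; -4.89 after scaling).

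The largest rises were those of Psca (0.624 to 778 TPM), Cck (0.464 to 434 TPM), Slc14a2 (0.133 to 257 TPM), Aldh1a3 (0.497 to 317 TPM), the mucin gene Muc20 (1.08 to 366 TPM) and Lypd2 (0.493 to 246 TPM). The largest falls were those of Pvalb (90.5 to 2.13 TPM), S100g (2644 to 96.1 TPM), Slc26a4 (85.8 to 3.01 TPM), Calb1 (357 to 17.1 TPM), Klk1 (4846 to 264 TPM) and Slc12a3 (583 to 30.2 TPM). These 12 kept their direction after scaling.

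All 8 thin limb genes rose on both scales (adjusted p = 0.0146, and 0.166 with an estimated correlation), and all 10 endothelial genes rose, or 9 with 1 falling after scaling (adjusted p = 0.0121, and 0.414 with an estimated correlation). Of the osmoadaptive genes, 10 of 11 rose on both scales (adjusted p = 0.0257, and 0.166 with an estimated correlation). Examples were Emcn (47.8 ± 5.02 to 587 ± 62.3 TPM), Akr1b3 (67.0 ± 9.91 to 3600 ± 944 TPM), Hspa1b (9.64 ± 3.38 to 517 ± 185 TPM) and Slc6a12 (0.0849 ± 0.0762 to 22.9 ± 8.10 TPM). The exception was Slc6a6, which fell from 112 to 90.7 TPM. All 8 urothelial genes rose on both scales, Upk1a from 1.81 to 35.9 TPM (adjusted p = 0.0346, and 0.527 with an estimated correlation). That call was lost without IM library 1, 3, 4 or 5, at adjusted p = 0.0829, 0.0656, 0.0684 and 0.0755. It was also lost with the pseudocount 0.1, at 0.0575, and in voom on the recovered reads, at 0.0888.

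All 12 convoluted proximal tubule genes and all 12 distal convoluted and connecting tubule genes fell on both scales (adjusted p = 1.41e-15 and 2.43e-14, each 0.125 with an estimated correlation), among them the organic anion transporter Slc22a6 (667 to 57.8 TPM). Of 9 genes of gluconeogenesis and fructose use 8 fell on both scales and Pck2 rose (adjusted p = 2.04e-06, and 0.148 with an estimated correlation). Fbp1 was 1590 ± 102 against 385 ± 138 TPM, with IM library 4 again the lowest of its zone in this list. All 15 oxidative phosphorylation genes fell, 10 under quantile normalization, when Atp5b and Cox4i1 lay above 0 (adjusted p = 6.22e-11, and 0.155 with an estimated correlation). Of 14 fatty acid oxidation genes 10 fell and Hadha rose, though all 14 fell after scaling (adjusted p = 3.94e-07, and 0.155 with an estimated correlation). Of 10 podocyte genes 5 fell and Cdkn1c and Podxl rose, with 9 and 1 after scaling, when Podxl fell (adjusted p = 0.00133, and 0.155 with an estimated correlation).

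Of 11 intercalated cell genes 6 fell and 4 rose, Slc4a1, Aqp6, Dmrt2 and Kit, with 7 and 3 after scaling (adjusted p = 0.00178, 0.315 with an estimated correlation, 0.122 after scaling and 0.0836 under quantile normalization). Of 8 straight proximal tubule genes 3 rose and 3 fell (1 and 4 after scaling), with a median log2 of -0.20 and a mean of 0.19, and camera called the list lower (adjusted p = 0.0302, and 0.564 with an estimated correlation). That call was lost after scaling (adjusted p = 0.368), under quantile normalization (0.832), in voom (0.0835) and without cortex library 1, OM library 1 and IM library 4 together (0.171). It was also lost without cortex library 1 (0.0856) or IM library 4 (0.0676) alone. Their levels of this list, 8.16 and 6.04, were the highest of cortex and the lowest of IM.

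The lists not called in the main test were again mixed. Of 10 thick ascending limb genes 7 rose and 1 fell (6 and 2 after scaling), with Umod at 942 ± 109 against 2510 ± 792 TPM. Of 10 principal cell genes 7 rose and Scnn1b and Scnn1g fell (7 and 3 after scaling). Water and urea transport genes rose in 8 of 10 cases and Aqp11 fell, with 8 and 2 after scaling. After scaling camera called the principal cell (up, adjusted p = 0.0414), water and urea transport (up, 0.00646) and prostaglandin lists (up, 0.0191). Quantile normalization called the same lists, at 0.0112, 0.00234 and 0.0275, and also the thick ascending limb (up, 0.0427, against 0.642 in the main test) and glycolysis (up, 0.0275, against 0.86 and pointing down). With no filter the prostaglandin list was called at 0.0267. Prostaglandin genes rose in 7 of 8 cases (8 adjusted over the list alone, 6 after scaling), with Ptger1 14.7-fold higher. Immediate early genes rose in 9 of 9 cases (8 after scaling, when Zfp36 lay at log2 -0.21). Counts of rises and falls were 10 and 3 of 16 for glycolysis (6 and 9 after scaling, when Aldoa fell), 5 and 4 of 10 for hypoxia (5 and 5), and 7 and 0 of 10 for fibroblast and matrix genes (5 and 1). They were 3 and 1 of 7 for smooth muscle and renin (1 and 2), 3 and 1 of 10 for leukocytes (2 and 5; 3 and 0 over the list alone), 2 and 0 of 7 for adipocyte genes, 2 and 0 of 7 for erythroid genes (0 and 0 after scaling and over the list alone) and 1 and 1 of 2 for adrenal cortex genes. The reads of the near-identical hemoglobin genes are uncertain. Adjusted over the list alone, all other counts of this comparison were as over all genes. Camera pointed down while median and mean lay above 0 for smooth muscle, leukocytes, adipocytes, erythroid genes, glycolysis and hypoxia.

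In limma 12972 of 15052 genes changed between IM and cortex, 10567 higher and 2405 lower in IM, and after scaling 11827 changed, 6030 higher and 5797 lower. At least a 2-fold change was met by 4741 genes higher and 933 lower, or 2149 and 1955 after scaling and 1841 and 1901 under quantile normalization. On the TPM scale, which holds the shift of the typical gene, the zones did not overlap for 11662 genes (77.5%, where chance gives 0.79%). Of the 12 lists called, 0 held with an estimated correlation, and 11 of 100 drawn splits of the 10 libraries called as many.

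**Figure D3:**
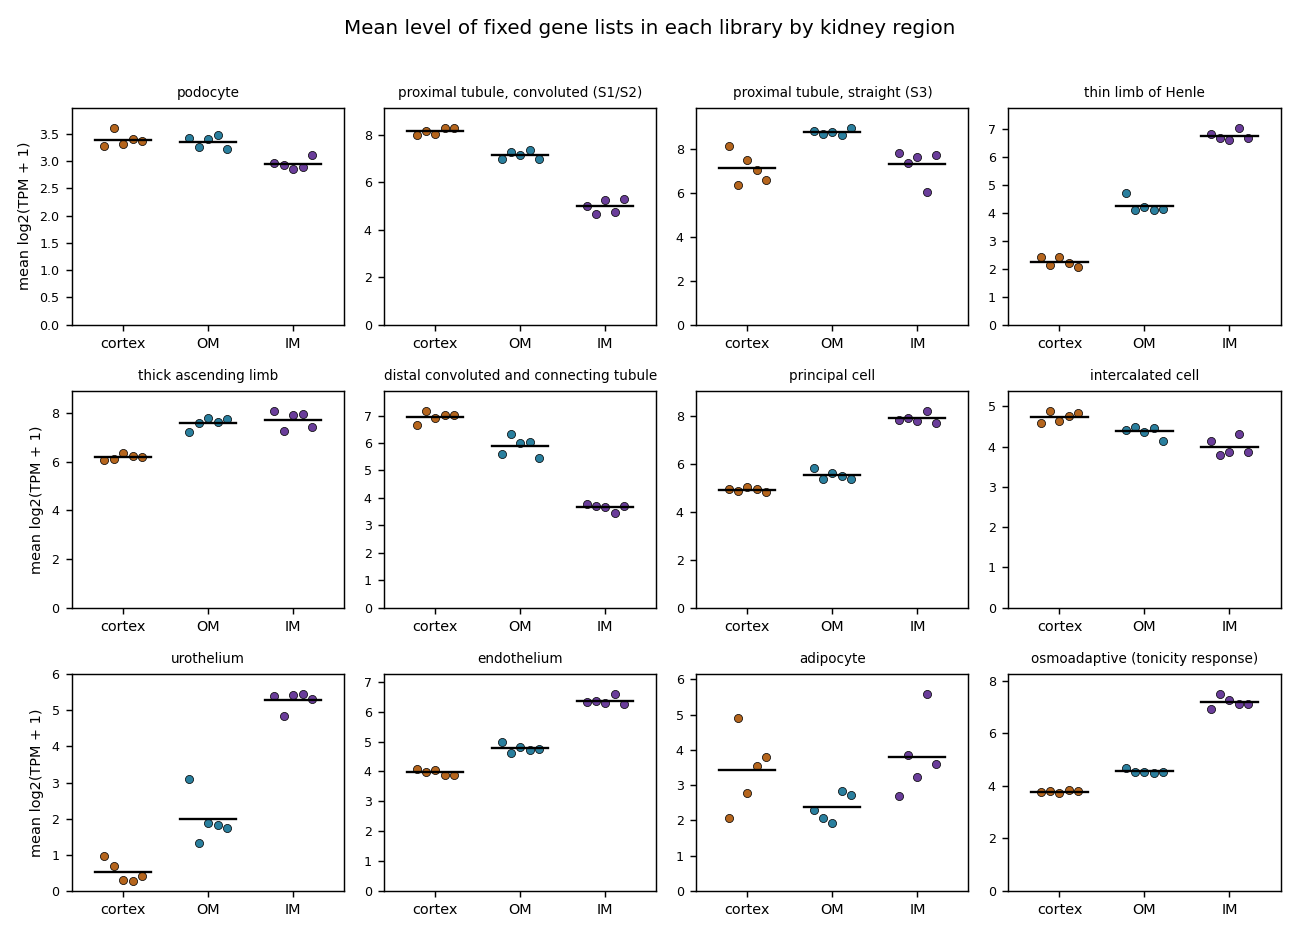
Mean log2(TPM + 1) of 12 of the fixed gene lists in each library, with 1 point per library and the mean of the zone as a bar (n = 5 per zone). The thin limb list averaged 2.24, 4.25 and 6.75 in cortex, OM and IM and the convoluted proximal tubule list 8.16, 7.13 and 5.00. IM library 4 was the highest of its zone in the adipocyte list (5.59), and OM library 1 in the urothelium list (3.11). All are on the TPM scale.

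Genes at least 2-fold higher in their zone than in each of the other zones numbered 68 in cortex, 66 in OM and 3153 in IM. After scaling they numbered 136, 94 and 1383, of which 68, 55 and 1383 were shared with the TPM scale. The cortex count was 108 with the pseudocount 0.1, 112 under quantile normalization and 124 in voom, the OM count 115 in voom and the IM count 1296 under quantile normalization. Cortex genes included Klk1, Cyp2e1, S100g, Slc5a2, Slc12a3 and Calb1, and IM genes included Aqp2, Cryab, Akr1b3 and Fxyd4. Acsm3 and Acadm were among the OM genes on the TPM scale and not after scaling. The OM count rested in part on a single library, since it was 34 without IM library 4.

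Along the anatomical order, 3339 genes rose at both steps inward, Slc14a2, Aqp1 and Slc5a3 among them, and 578 fell at both steps, such as Slc34a1, Slc5a2 and Slc12a3. A further 423 were highest in OM, such as Napsa and Crot, and 193 lowest in OM, such as Ptges. After scaling these classes held 1487, 1755, 489 and 335 genes, with 1479, 578, 235 and 56 shared, and Aqp1 left the rising class because it fell from OM to IM (log2 -0.23). Both steps use the same OM libraries. Independent lists of the observed sizes would give 2835 rising, 163 falling, 735 peaked and 630 lowest genes. In 20 simulations of unchanged zones each class held at most 0 genes. No gene changed in these simulations, so they cannot show what sharing the OM libraries adds for genes that do change. With the OM libraries divided between the steps, the medians over 20 divisions were 2714, 577, 358 and 126.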

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

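The tests of tissue carry-over and of the adipocyte genes were chosen after the levels had been seen, and the tests of the shift of the typical gene and of other splits of the libraries were chosen before their results. In 192 groups of 5 libraries (25 list levels, the depth, the share of Kap and 37 named genes in each zone), 16 held a library whose gap to the nearest other exceeded 0.71 of the group's range, where chance at 1 in 20 gives about 9.6.

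OM library 1 stood apart in 7 of these groups, being high for the thin limb list (4.69 against 4.09 to 4.20, mean log2(TPM + 1)), the smooth muscle and renin list (4.93 against 4.14 to 4.34), Akr1b3 (148 against 67.7 to 87.4 TPM), Aldh1a3 (6.90 against 0.625 to 1.68 TPM), Psca (37.0 against 1.66 to 5.00 TPM), Sptssb (7.89 against 0.209 to 0.660 TPM) and Muc20 (13.1 against 7.63 to 8.49 TPM). IM library 4 was low for the straight proximal tubule list (6.04 against 7.35 to 7.82) and for gluconeogenesis and fructose use (6.43 against 7.18 to 7.48), and high for Sptssb (156 against 123 to 130 TPM). IM library 2 was low for the urothelium list (4.84 against 5.32 to 5.46), and OM library 2 was high for oxidative phosphorylation (9.54 against 9.46 to 9.48). Among cortex libraries, library 3 was high for Slc14a2 (0.422 against 0.0195 to 0.108 TPM), Slc12a1 (198 against 140 to 155 TPM) and Slc5a3 (13.9 against 12 to 12.1 TPM), and library 1 for Sptssb (1.45 against 0 to 0.191 TPM).

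The first pattern is the rise of the typical gene in IM, by a median of 0.652 (log2) over cortex. Without the 100 most abundant genes, and with each library rescaled, the median was still 0.454 (SD 0.035 over the 5 IM libraries), so those genes account for part of it and not the whole. With every library thinned to the 16264486 reads of the smallest, it was 0.654 (SD 0.056), which argues against depth. In 3 equal groups of genes by relative length, from shortest to longest, it was 0.431 (SD 0.04), 0.667 and 0.785, above the bound of 0.1 in each, so gene length bias alone would not give it. The IM libraries did spread TPM more evenly, with the 100 most abundant genes of a library at a mean of 21.4%, against 32.7% in cortex. Whether the RNA of IM cells is itself spread more evenly stays open as a biological hypothesis. With no spike-in reads, no absolute change can be read from the shift.

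The second pattern is the presence of thick ascending limb and proximal tubule transcripts in IM, Slc12a1 at 958 TPM and Slc7a13 at 442 TPM. Carry-over of whole OM tissue as the only source would lower both lists alike from their OM levels, but the thick ascending limb list lay 1.61 (SE 0.39) above the straight proximal tubule list relative to OM, and above it in all 5 IM libraries. Carry-over of whole cortex would lower both proximal tubule lists alike, but the straight segment lay 3.35 (SE 0.27) above the convoluted segment relative to cortex. The SEs of 0.39 and 0.27 cover the IM libraries only and take the OM or cortex mean as exact. Over the cortex libraries the straight list had an SD of 0.72. The SE of 0.19 given next covers both IM and OM. Inner stripe tissue in the IM pieces, or thick limb cells that reach into them, stays open and the pair was not separated, since the thick ascending limb list lay 0.14 (SE 0.19) above OM on the TPM scale but at -0.40 (SE 0.19), below OM by just over 2 SE, after median-ratio scaling, which left the other differences at 1.61 and 3.32. A biological source in IM itself is among the open explanations and was not tested. Whether the OM pieces, used here as the reference, held cortex tissue was not tested either. The podocyte list stood at a mean log2(TPM + 1) of 3.36 in OM against 3.4 in cortex, so this caveat bears on the OM levels.

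The third pattern is the high adipocyte level of IM library 4, which the gap rule above did not flag. All 7 tested adipocyte genes were highest there among IM libraries. Fabp4 was at 698 TPM, Cfd at 130 TPM and Adipoq at 26.9 TPM, against 1.19 to 4.23 TPM for Adipoq in the others. Attached fat would give this, but the count restates the high level of the same list and is no separate test. Fat tissue attached to the piece is a candidate source, though Fabp4 was at 353 TPM or more in the other IM libraries as well, and all 7 adipocyte genes were also highest in 1 library of cortex, library 2. A mislabelled sample is argued against, because the library's mean correlation with the other IM libraries exceeded that with the nearest other zone, OM, by 0.126 over the 15052 tested genes (0.977 against 0.85; SD of the difference 0.017 over the other IM libraries) and by 0.053 over all 25030 genes (0.991 against 0.938; SD 0.007), the latter chosen after seeing the data. No biological explanation was tested, as the labels give no difference between libraries of a zone.

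Other splits of the same libraries into groups of 5 were drawn 100 times, the real one included. For OM against cortex, fitted on those 10 libraries, the real split called 6037 genes and the highest other split 2. These values were 12405 and 1 for IM against OM, and 12905 and 1 for IM against cortex. Thus 1 of 100 splits was as large each time, the smallest share possible with the real split included. A chance labelling of these libraries is excluded at 0.05 as the source of these counts. The other splits mix the zones, which adds the zone difference to the spread and keeps their counts low. For splits of all 15 libraries into the 3 zones, the real counts and the highest others were 68 and 0 for genes enriched in cortex, 3153 and 1 for IM, and 3917 and 0 for genes falling or rising at both steps (1 of 100 each). For genes enriched in OM, 2 of 100 splits reached the real 66, which is under the bound of 0.05 for a chance labelling. The other split called 1593 genes and put 4 IM libraries and 1 OM library in the group standing for OM, so it followed the structure of the zones. The number of gene lists called was not beyond that of other splits. For OM against cortex, 14 of 100 splits called at least the real 13 (highest other 16). For IM against OM 43 called at least 11 (highest other 15), and for IM against cortex 11 called at least 12 (highest other 13). Each other split still set unequal numbers of libraries of each zone against each other, so part of the zone difference remained in it. These splits therefore cannot show what chance alone would give, and chance is not excluded for these numbers of lists.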

How the results depend on the processing

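Median-ratio scaling, voom on the recovered reads and the fit without cortex 1, OM 1 and IM 4 were chosen after seeing the data; the other alternatives were set in advance. The planned count-based alternatives (other size factors, a Wald test on counts, no filter on counts and a fold threshold on counts) were not run. The table holds TPM, and the voom fit was the only alternative run on the recovered reads.

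The counts of changed genes stayed within 1.5 times of their values of 5216, 12591 and 12972 (OM against cortex, IM against OM and IM against cortex) under every alternative run. Leaving out single libraries gave 4452 to 5522, 11934 to 12572 and 12416 to 13036, and leaving out cortex 1, OM 1 and IM 4 together gave 5531, 11776 and 12330. Voom called 4852, 12067 and 12519 genes, with 4595, 11399 and 11824 shared in direction and 0 opposite. Voom used the plain read totals as library sizes, so its scale is set by totals, as that of TPM is. Its calls therefore do not check the split into higher and lower genes. With the replicate block the counts were 5524, 12736 and 13114, of which 5038, 12525 and 12916 were shared. With it, camera also called the erythroid list in OM against cortex (adjusted p = 0.00497, against 0.406 without), and urothelium (0.0383, against 0.0579) and smooth muscle and renin (0.0421, against 0.0813) in IM against OM. The labels do not say what a number marks, and the numbers missed the bar set for pairing, every correlation over 0.1: of 15 same-numbered pairs 8 had residual correlations over 0.1 (-0.027 to 0.262). Even so 10 of 15 correlated best with their own number, a hint of pairing from the data, not the design. Quantile normalization called glycolysis upward in OM against cortex (0.00153) and in IM against cortex (0.0275, where the main test pointed down), water and urea transport in IM against OM (0.0149) and the thick ascending limb in IM against cortex (0.0427), none of them called in the main test, and the cause was not tested.

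The split into higher and lower genes moved with the scaling. Quantile normalization gave 1846 higher and 2218 lower genes for OM against cortex, 5543 and 5427 for IM against OM and 5552 and 5867 for IM against cortex. At least 2-fold, it gave 124 lower for the first, 1391 and 1628 for the second and 1841 and 1901 for the third, with 112 genes enriched in cortex, 1296 in IM, 1373 falling, 1032 rising and 364 lowest in OM. Median-ratio scaling gave 2481 and 2559, 5706 and 5498, and 6030 and 5797, at least 2-fold 145 lower, 1445 and 1632, and 2149 and 1955, with 136 enriched in cortex, 1383 in IM, 1755 falling, 1487 rising and 335 lowest in OM. The share of higher genes went from 81.8%, 79.4% and 81.5% to 49.2%, 50.9% and 51.0% under median-ratio scaling and 45.4%, 50.5% and 48.6% under quantile normalization.

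With the pseudocount 0.1, 940 genes were at least 2-fold higher and 123 lower in OM than in cortex and 108 were enriched in cortex. Voom gave 935, 137 and 124, and 115 enriched in OM. Genes enriched in OM ranged from 34 (without IM library 4) to 81 (without cortex library 1), and the cause was not tested. With an estimated correlation 4, 0 and 0 lists were called in place of 13, 11 and 12, and fry, which does not compare a list with other genes, called 17, 19 and 20.

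Turns in direction were counted only where the main fit or the alternative called the gene. Others were left out, such as Ptger3 from OM to IM (0.199 to -0.335 under median-ratio scaling). Of 292 named values, 11 had a counted turn under median-ratio scaling and 11 under quantile normalization. Under the first they were, from OM to IM, Slc12a1 (-0.52), Aqp1 (-0.23), Podxl (-0.31), Lyz2 (-0.006) and Aldoa (-0.008), and, from cortex to IM, Podxl (-0.30), Tagln (-0.15), Csf1r (-0.06), Aldoa (-0.14), Zfp36 (-0.21) and Hadha (-0.40). Under the second they were, from OM to IM, Podxl (-0.18) and Star (-0.15), and, from cortex to IM, Podxl (-0.11), Dcn (-0.082), Tagln (-0.007), Csf1r (-0.06), Star (-0.065), Atp5b (0.043), Cox4i1 (0.065), Zfp36 (-0.096) and Kit (-0.091). Without single libraries 0 values had a counted turn. Median-ratio scaling divides each library by 1 factor, so it moves the differences of abundant genes alike, and small rises could turn to falls. From OM to IM, Slc12a1 went from 0.024 to -0.52 and Aldoa from 0.537 to -0.008. The cause of the turns under quantile normalization was not tested. Depth limits genes of few reads most: at 1 TPM a library held a median of 20.9 to 33 reads.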

Other observations

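The families here were picked after their values were seen, and all differences are between IM and cortex unless stated. Wnt ligand genes, which encode secreted signals, were mostly higher in IM: of 11 tested, 10 rose and Wnt5b fell, with 9 and 1 after median-ratio scaling, and the median difference was 2.57 (log2), or 2.21 after scaling. Wnt7b went from 0.377 ± 0.160 TPM in cortex through 7.97 ± 0.349 in OM to 129 ± 29.6 in IM, Wnt4 from 0.410 ± 0.154 through 1.49 ± 0.719 to 95.9 ± 13.9 and Wnt9b from 0.609 ± 0.150 through 2.10 ± 0.352 to 75.4 ± 13.7 (SD, n = 5 per zone). Hox cluster genes, transcription factors that pattern the body axis, rose in 28 of 30 cases and Hoxc10 fell, but after scaling 17 rose and 5 fell, with a median of 0.94 against 0.28. Examples of members higher in IM on both scales were Hoxb9 (11.6 ± 1.16 to 144 ± 27.6 TPM), Hoxb6 (39.5 ± 4.60 to 251 ± 38.0 TPM) and Hoxd4 (18.6 ± 1.46 to 111 ± 9.60 TPM).

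Claudins, which set the permeability of tight junctions, divided: 11 of 16 rose and 4 fell (9 and 4 after scaling). Cldn4, Cldn8 (42.7 ± 3.92 to 337 ± 33.9 TPM), Cldn7 and Cldn15 (6.84 ± 1.91 to 101 ± 15.2 TPM) were higher in IM, and Cldn2, a claudin of the proximal tubule, was lower (352 ± 15.4 to 94.2 ± 31.3 TPM), all in the same direction after scaling. Of 10 keratin genes 9 rose and 0 fell, with 9 and 1 (Krt10) after scaling, and Krt18 went from 15.9 ± 3.20 to 346 ± 50.5 TPM. Between OM and both other zones, Napsa, the gene of the protease napsin A, stood highest in OM on both scales, at 1557 ± 597, 4800 ± 542 and 1942 ± 780 TPM in cortex, OM and IM, and so did Crot, a peroxisomal carnitine acyltransferase, at 190 ± 66.5, 520 ± 61.4 and 231 ± 74.1 TPM.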
